A study of Homo sapiens with 6 samples.

How the data were processed

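RNA sequencing was performed on 6 cultures of TPC-1-Len, a line of human papillary thyroid carcinoma cells (TPC-1) made resistant to lenvatinib and kept in 10 µM of the drug. The cells had been transfected with a control short hairpin RNA (shNC, 3 cultures) or with a hairpin against KRT15 (shKRT15, 3 cultures). Per the labels' protocols, RNA was extracted with TRIzol, and a service provider purified mRNA, fragmented it and built Illumina libraries. The deposited values are raw read counts per gene, 1 whole number per gene and library, and no normalization had been applied to them. Per the submitters' processing notes the genome build was GRCh38. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Without a strand setting, reads of a gene and of an antisense partner cannot be separated. Genes with many near-identical copies, such as ferritin, KRT18 and ribosomal protein genes, may have lost or gained reads to those copies.

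The deposited table held counts for 22681 genes, 16031 of them given as protein coding, and the gene with the fewest reads had 1 read over the 6 libraries. The total count per library was 36286059 to 36808695 in shNC and 39868231 to 41343780 in shKRT15. Each library was placed in its group by its title. No library pair agreed within sampling noise: a chi-square statistic per degree of freedom over genes was 6.24 to 31.1 between libraries of 1 group and 183 to 211 between libraries of different groups. All 6 libraries therefore entered as separate samples. The design text calls them biological replicates without saying whether they came from separate transfections, so p-values measure the spread between these cultures.

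Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimation. Library sizes were scaled by TMM. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14356 genes. The model held the group as its only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values given for genes come from this test. Log2 fold changes are shKRT15 over shNC with their standard error (SE), and levels are CPM, read counts scaled to library size with TMM factors. Fold changes of genes with 1 to 3 reads in a group were replaced by the ratio of summed counts with an exact 95% interval, which covers counting error only.

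Before the data were examined, 45 gene lists with 887 different genes were written, covering keratins, thyroid genes, drug targets, growth signalling, adhesion, stress, metabolism, RNA quality and other cell types. They matched 855 genes of the table, and 42 lists had at least 5 tested members. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 42 lists. Adjusted p-values given for lists come from that test unless another is named. The same test with the correlation estimated for each list and the rotation test fry were run beside it. Fry asks whether the members of a list changed at all, so its calls do not set a list apart from other genes. Some genes stood on more than 1 list. The test, the design, the other settings compared and the rule for naming genes were also set before the data were examined. The rule took KRT15 and its relatives KRT14, KRT16, KRT17 and KRT19, whatever their values. Among called genes with a mean of at least 1 CPM, a gene symbol and groups that did not overlap, it took the 10 largest rises, the 10 largest falls and the 5 smallest p-values in each direction. It also took the 4 members of each described list with the smallest p-values. Some genes that the rule took are not reported here. A list was described if its test or a share of 0.333 of its members passed the threshold, or if it belonged to a set fixed in advance. As 45% of all tested genes were called, a share of 0.333 does not set a list apart from other genes. The Notch list met none of these and is given so that every tested list is reported. Other genes named as the exceptions of their list, and KRT34, KRT79, KRT222, KRT33B, KRT78, FGFR1, RET, ROR1, CCL3L3, CDKN2A, LMNB1, HMGB2 and the RNA-binding protein genes, were chosen after their values were seen.

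The settings set in advance for comparison were size factors in place of TMM, DESeq2 1.42.0, limma-voom, no filter on low counts, a minimum of 1 CPM in 3 libraries, the replicate number as a block, protein-coding genes only, removal of the GC content and length trend of each library, and leaving out each library in turn. Upper-quartile scaling, total-count scaling, leaving out the 50 most abundant genes and leaving out mitochondrially encoded genes were added after the data were seen. GC content and length were taken from GENCODE release 29 and were available for 94.4% of tested genes. The fit was checked on counts simulated from the means and library sizes of this comparison over 14152 genes. The edgeR test recovered 55.2% of 67 genes changed 1.5-fold, 91% of 67 genes changed 2-fold and 95.5% of 66 genes changed 4-fold, with 4.73% false calls. Only 200 genes were changed there, with dispersions fitted to these data, whereas 45% of tested genes were called in the data. The share of false calls was not checked for so wide a change. A simulated list shifted 1.3-fold was called and 0 of 41 random lists were. Genes were drawn independently of each other there, so the check does not cover list calls among genes that vary together. With a GC content trend placed on the simulated shKRT15 libraries, 3478 unchanged genes were called, against 19 with the trend removed. The size of that trend was not taken from these data. The scan of 3' UTR 7-mers ranked 5 of 5 placed 7-mers first, over 12554 genes, with a placed fall of 0.3 (log2). The leading 7-mer in the data had a median shift of −0.0376, and the scan was not checked at that size. Figures were drawn with matplotlib 3.10.9.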

Results

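The transcriptomes of lenvatinib-resistant TPC-1 cells with a control hairpin (shNC, n = 3) and with a hairpin against KRT15 (shKRT15, n = 3) were compared. Every culture was resistant and kept in the drug, with no sensitive or untreated cultures beside them. The comparison therefore cannot tie a gene to resistance, and genes that differ between the hairpins need not depend on KRT15. TPC-1 is a papillary thyroid carcinoma line. Lenvatinib inhibits the VEGF, FGF and PDGF receptor kinases, KIT and RET, and was present in both groups at 10 µM. KRT15 encodes a type I keratin, an intermediate filament protein of basal epithelial cells. Libraries held 36286059 to 41343780 counted reads. The first principal component held 65.7% of the variance and the next one 10.7%.

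KRT15 fell by 23.4% (95% confidence interval 11.3 to 33.9%) in cells with its hairpin. Its level was 32.3 ± 3.77 CPM (SD, n = 3) in shNC and 24.7 ± 0.365 CPM (SD, n = 3) in shKRT15. The 3 shNC libraries held 1040, 1137 and 1284 KRT15 reads and the 3 shKRT15 libraries 1024, 1044 and 1005. In the edgeR quasi-likelihood test the log2 fold change was −0.38 ± 0.10 (SE) with a Benjamini-Hochberg adjusted p of 0.00465. The groups did not overlap in CPM, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. KRT15 lies on the minus strand of chromosome 17, within the type I keratin cluster. Its span in GRCh38 is 41513743 to 41522529 in GENCODE release 29 and 41513745 to 41518890 in RefSeq. The counts are per gene without separating exons or UTRs, and which span they cover is not known. The sequence of the hairpin and its site in the transcript are not given in the sources used here.

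**Figure D1:**
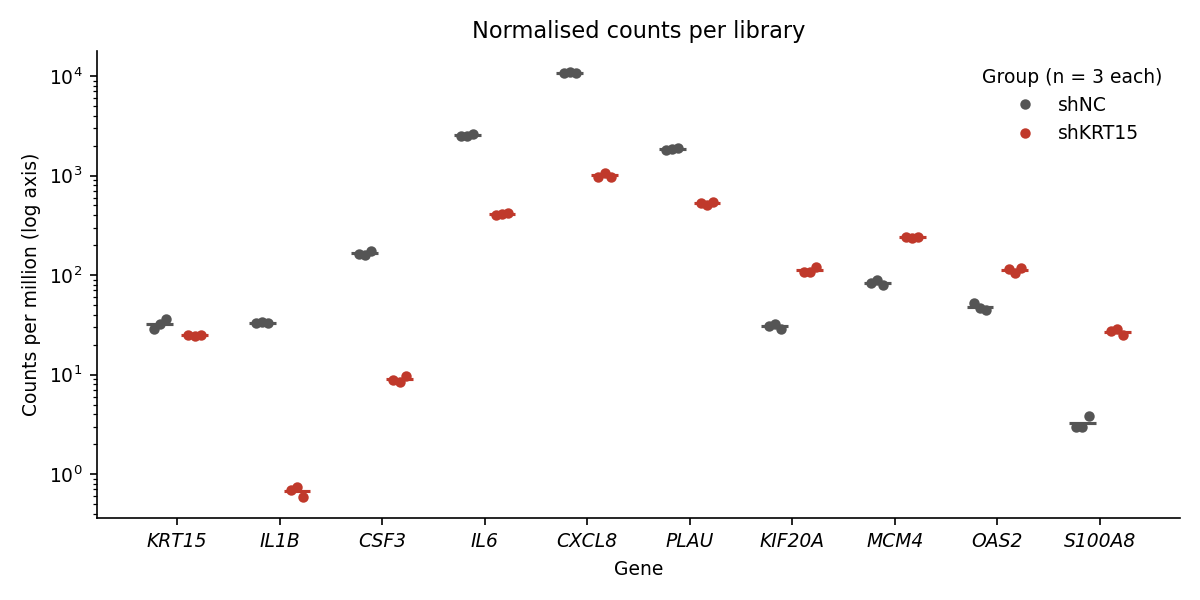
CPM on a log axis for 10 genes in each library, with shNC in grey and shKRT15 in red. Points are libraries (n = 3 per group) and bars are group means. KRT15 moves from a mean of 32.3 to 24.7 CPM, CXCL8 from 10830 to 1004 CPM and MCM4 from 84.1 to 238.5 CPM.

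Among other keratins, several rose and the closest relatives of KRT15 were nearly absent. KRT18, the type I partner in simple epithelia, rose by 0.89 ± 0.07 (SE) on the log2 scale (adjusted p = 1.37e-08), and the other tested members of the type I list, KRT10 (0.13 ± 0.10, adjusted p = 0.35) and KRT17 (0.32 ± 0.51, adjusted p = 0.639), did not pass the test. KRT10 was called without shNC replicate 3 (0.24, adjusted p = 0.0492), and KRT17 turned to −0.11 without shKRT15 replicate 1. The close relatives KRT14, KRT16 and KRT19 had 0, 0 and 4 reads over the shNC libraries and 2, 10 and 0 over the shKRT15 libraries. Of 5 tested members of the type II list, 3 rose and none fell: KRT80 (1.23 ± 0.08), KRT81 (0.64 ± 0.09) and KRT86 (0.75 ± 0.11), with the same 3 adjusted over the list alone. KRT81 and KRT86 are near-identical hair keratins whose reads may have been split between them. KRT8 was at 0.20 ± 0.12 and KRT7 at −0.03 ± 0.11. The type II list was called (adjusted p = 0.0329), with adjusted p = 0.358 with an estimated correlation. The call was also lost without shNC replicate 2 (adjusted p = 0.362) and without shKRT15 replicate 1 (0.212), 2 (0.195) or 3 (0.207), with no filter on low counts (0.1055) and with the GC content and length trend removed (0.327). Outside the lists, the type I hair keratin KRT34 fell by 2.21 ± 0.19 on the log2 scale, and the type II keratin KRT79 fell by 1.36 ± 0.47 (adjusted p = 0.0272). The call of KRT79 was lost without shNC replicate 1 (adjusted p = 0.0833), shKRT15 replicate 1 (0.0968) or shKRT15 replicate 3 (0.109). The type I keratins KRT222 (0.28 ± 0.23) and KRT33B (0.26 ± 0.65) and the type II keratin KRT78 (0.21 ± 0.32) did not pass, though KRT222 was called with the trend removed (0.58, adjusted p = 0.0450).

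Expression changed widely. Of 14356 genes tested, 3169 rose and 3295 fell in shKRT15, 45% of all, and 568 rose and 717 fell by at least 2-fold. Counts of called list members are to be read against that 45%. The same holds for calls by fry, which does not compare a list with other genes and called 6 lists higher and 19 lower. Lists with a smaller share called included heat shock genes (40%), WNT targets (40%) and the microRNA and hairpin machinery (38.5%). The 2 groups did not overlap in 54% of all tested genes, where chance gives 10%. They did not overlap in 96.1% of the called genes, which were chosen by a test on the same libraries. KRT15 ranked 4062 by p-value, and 4528 called genes had a larger fold change than it. The fold changes followed GC content across genes, with a Spearman correlation of 0.246 over 13526 genes, which are not independent replicates. After the GC content and length trend was removed, 5262 of the 6464 called genes were still called in the same direction.

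The largest rises were in S100A9, a subunit of calprotectin (log2 fold change 5.16 ± 0.35, from 0.288 to 10.4 CPM), the plasma membrane calcium pump gene ATP2B2 (3.98 ± 0.37), the B-cell transcription factor gene PAX5 (3.60 ± 0.22) and CDH16, the kidney and thyroid cadherin (3.55 ± 0.36). They were followed by SLC17A3, CDC42BPG, NFE2, ADAMTS15, NOX5 and PALM3 at 3.32 to 3.47. Apart from NOX5, these followers had shNC means of only 0.1955 (PALM3) to 1.257 CPM (ADAMTS15). CDC42BPG had 1, 4 and 17 reads in the shNC libraries. The shNC means of ATP2B2 (0.1953 CPM), PAX5 (0.7273 CPM) and CDH16 (0.6652 CPM) were also low. NOX5, a calcium-activated NADPH oxidase, went from 5.70 to 60.3 CPM. The other calprotectin subunit S100A8 (3.05 ± 0.13) rose from 3.27 to 27.1 CPM, and with the mitotic kinesin KIF20A, NOX5, MCM4 and DPYSL3 it had the smallest p-values among rises.

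The largest falls were in the carbonic anhydrase-related gene CA8, with 452 reads in shNC and 2 in shKRT15 (a ratio of 262, interval 72.1 to 2170), and in ROR1-AS1, with 282 reads and 1 read (a ratio of 327, interval 58.2 to 13000). ROR1-AS1 is antisense to ROR1, which itself rose by 0.30 ± 0.11 (adjusted p = 0.0322, but 0.0775 to 0.116 without shNC replicate 2 or 3 or shKRT15 replicate 1 or 2), and its strand was not separable. Next came the plasminogen activator inhibitor SERPINB2 (−6.11 ± 0.22), PNLIPRP3 (−5.81 ± 0.30), the cytokine genes IL1B (−5.61 ± 0.14), CCL20 (−5.48 ± 0.14) and IL36G (−5.30 ± 0.15), and RCSD1, GNA15 and LRRC15 at −5.42 to −5.07. The smallest p-values of all were those of SERPINB7 (from 391.7 to 23.3 CPM), CCL3 (from 1806 to 86.6 CPM), CSF3, the protease inhibitor TFPI2 (from 1907 to 193 CPM) and CXCL8 (from 10830 to 1004 CPM). CCL3 shares sequence with CCL3L3, which fell by 3.47 ± 0.08, and the split of reads between them is uncertain.

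**Figure D2:**
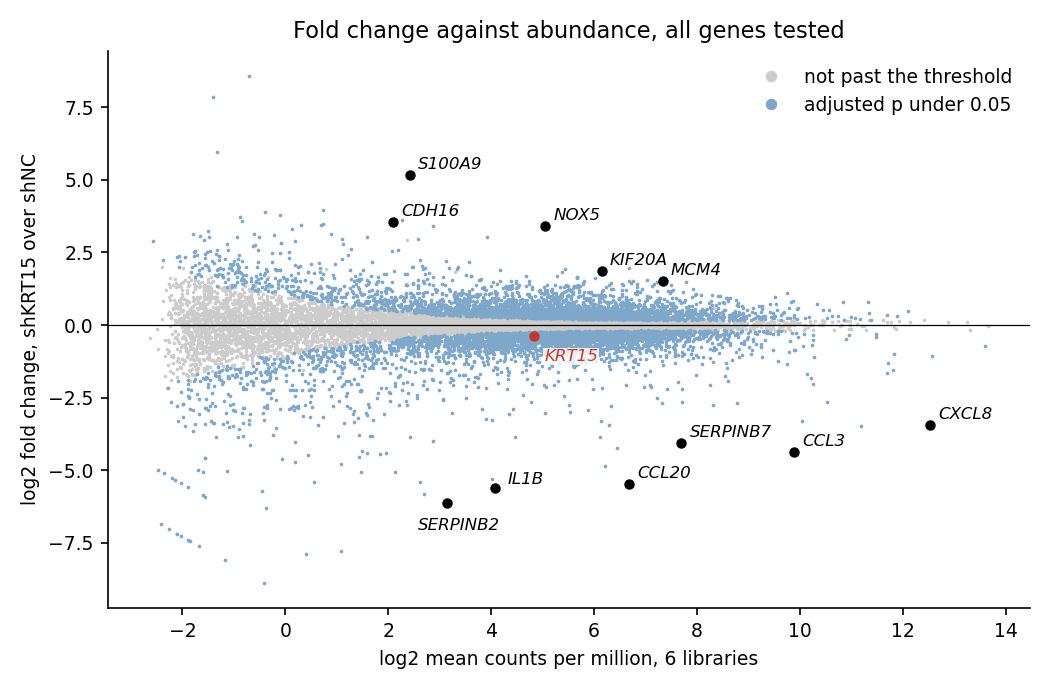
Log2 fold change (shKRT15 over shNC) against log2 mean CPM over the 6 libraries for the 14356 genes tested, with genes at an adjusted p under 0.05 in blue and others in grey. KRT15 (red) sits at −0.38 amid the body of called genes, and CXCL8, among the most abundant genes, sits at −3.43.

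Genes of NF-kB signalling and inflammatory cytokines fell together. Of 29 tested members, 27 fell, none rose and 2 (LCN2 and IL33) did not pass the test, with the same counts adjusted over the list alone. LCN2 was called higher without shNC replicate 3 (0.19, adjusted p = 0.0293) and with total-count scaling (0.19, adjusted p = 0.04999). The median log2 fold change was −1.66 (adjusted p = 1.73e-18, and adjusted p = 0.0466 with an estimated correlation). The granulocyte growth factor CSF3 (−4.22 ± 0.09), the neutrophil chemokine CXCL8 (−3.43 ± 0.08), IL1B and IL6 (−2.64 ± 0.07) led the list. In the leukocyte list, CSF1R fell from 3.54 to 0.862 CPM, CD68 from 87.9 to 59.6 CPM and LYZ from 0.541 to 0.0494 CPM, while LAPTM5 stood at 116 and 110 CPM and was called lower (−0.23) with the GC content and length trend removed. That list was not called (3 of 5 lower, also adjusted over the list alone, adjusted p = 0.0924), but was called without shNC replicate 2 (adjusted p = 0.0316), without shKRT15 replicate 1 (0.0290) and without shKRT15 replicate 3 (0.0149). It was also called with no filter on low counts (median −1.62, adjusted p = 0.0169), with the GC content and length trend removed (−0.69, adjusted p = 0.0413) and by fry (adjusted p = 0.00605).

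Cell-cycle genes rose. Of 25 tested G1-S replication genes, 24 rose and only CCNE1 did not pass, at a median of 1.34 (adjusted p = 4.52e-15, and adjusted p = 0.0466 with an estimated correlation). The replicative helicase genes MCM4 (2.84-fold, from 84.1 to 238.5 CPM) and MCM2 (1.63 ± 0.09), TYMS (1.42 ± 0.07), which makes thymidylate, and TK1 (1.93 ± 0.10) led them. Of 28 G2-M mitotic genes, 27 rose and only CENPE (−0.33, adjusted p = 0.151) did not pass, at a median of 1.03 (adjusted p = 1.85e-14, and adjusted p = 0.0466 with an estimated correlation). KIF20A (1.86 ± 0.08), PRC1 (1.33 ± 0.07), BIRC5 (1.45 ± 0.08) and CDC20 (1.36 ± 0.08) led this list. CENPE was called lower without shKRT15 replicate 2 (−0.56, adjusted p = 0.00844) and with no filter on low counts (adjusted p = 0.00927). Adjusted over the list alone the counts were again 24 and 27. Replication-dependent histone genes, which mRNA purification captures poorly, did not move with them: of 14, 1 rose and 4 fell, among them H2BC12 (−1.35 ± 0.08) and H2BC4 (−1.42 ± 0.13), the same adjusted over the list alone, and the list was not called (adjusted p = 0.307), though fry gave adjusted p = 0.000555.

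Interferon-stimulated genes rose in the main. Of 33 members 24 rose, 3 fell (IFI44, DDX60 and DDX58) and 6 did not pass, the same adjusted over the list alone, with a median of 0.50 (adjusted p = 4.99e-06, and adjusted p = 0.152 with an estimated correlation). OAS2 (1.23 ± 0.08), OAS1 (1.10 ± 0.08) and OAS3 (1.01 ± 0.08), which sense double-stranded RNA, were among those that rose. DDX60 lost its call with the GC content and length trend removed (adjusted p = 0.314), with total-count scaling (0.0745) and without shNC replicate 1 or 2 or shKRT15 replicate 1 or 3 (0.0599 to 0.0829). Of 17 genes of class I antigen presentation, 5 rose, among them CALR (0.60 ± 0.08) and NLRC5 (0.52 ± 0.10), and 7 fell, among them ERAP2 (−0.49 ± 0.08) and TAP1 (−0.45 ± 0.08). Of 8 immune checkpoint and MHC class II genes, CIITA rose and 4 fell, including the PD-1 ligands CD274 (−2.05 ± 0.10) and PDCD1LG2 (−1.68 ± 0.10). Neither of these 2 lists was called, but the checkpoint list was with DESeq2 (adjusted p = 0.00747) and by fry (adjusted p = 0.000888, lower), and the counts were the same adjusted over the list alone.

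Among the listed lenvatinib target kinases, 5 of 6 tested genes rose, by 0.80 to 1.05 for FGFR2, FGFR3, FGFR4 and PDGFRB (SE 0.18 to 0.26) and by 0.19 ± 0.07 for FGFR1. The list held 11 genes, and neither a VEGF receptor gene nor KIT was among the 6 tested. Levels were low for PDGFRB (1.47 to 3.06 CPM), FGFR3 (2.30 to 4.19 CPM) and FGFR2 (2.84 to 4.97 CPM). RET, the receptor rearranged in TPC-1, fell by 0.26 ± 0.08. The call of FGFR1 was lost with the GC content and length trend removed (0.04, adjusted p = 0.711) and without shNC replicate 2 or 3 or shKRT15 replicate 1 or 3 (adjusted p = 0.0555 to 0.136), and that of RET without shNC replicate 2 (0.1135) and with total-count scaling (0.053). The counts were the same adjusted over the list alone, and the list was not called (adjusted p = 0.0575), though fry gave adjusted p = 0.00478. Of 16 angiogenic ligands, 10 fell and only FGF2 rose, with a median of −0.57 (adjusted p = 0.000466, and adjusted p = 0.135 with an estimated correlation) and the same counts adjusted over the list alone. They included CXCL8, HBEGF (−2.99 ± 0.13), VEGFC (−1.20 ± 0.07) and FGF1 (−1.56 ± 0.10). Receptor kinases that can bypass the drug and their ligands moved both ways: of 20, 6 rose, with AXL (0.71 ± 0.07) and ERBB2 (0.57 ± 0.09) leading, and 4 fell, with HBEGF and IGF2 (−0.86 ± 0.10) leading. Of 14 drug efflux transporters, 2 rose (ABCA2, 0.95 ± 0.08, and ABCC4, 0.64 ± 0.09) and 8 fell, led by ABCA1 (−1.74 ± 0.10) and ABCC3 (−0.69 ± 0.08), and the list was not called (adjusted p = 0.0924, but 0.0498 with the GC content and length trend removed and 0.0121, lower, by fry), with 6 members past the threshold without shNC replicate 1. Both lists kept these counts adjusted over the list alone.

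Genes of MAPK output fell more often than they rose. Of 22 members, 11 fell and 2 rose (ETV1 and EPHA4, the latter not called without shNC replicate 2 or 3 or shKRT15 replicate 1 or 3, adjusted p = 0.0542 to 0.151), at a median of −0.23 (adjusted p = 0.012, and adjusted p = 0.311 with an estimated correlation), the same adjusted over the list alone. IL11 (−3.42 ± 0.09), the ERK phosphatase DUSP5 (−1.36 ± 0.08), IER3 (−1.30 ± 0.08) and LIF (−1.08 ± 0.07) led the falls. Of 18 immediate early genes, 11 fell and KLF4 rose (13 and 2 adjusted over the list alone), with DUSP1 (−0.85 ± 0.07), KLF6 (−0.83 ± 0.07) and JUN (−0.70 ± 0.07) as examples (adjusted p = 0.00197, and adjusted p = 0.152 with an estimated correlation). KLF4, at 0.22 ± 0.07, was no longer called without shNC replicate 2 (adjusted p = 0.0533) or with the GC content and length trend removed (0.0853, adjusted p = 0.316). Of 15 PI3K-FOXO targets, TXNIP (1.13 ± 0.08) rose and 8 fell, among them PIK3IP1 (−1.25 ± 0.12), KLF9 and BCL6, with no call for the list and the same counts adjusted over the list alone.

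**Figure D3:**
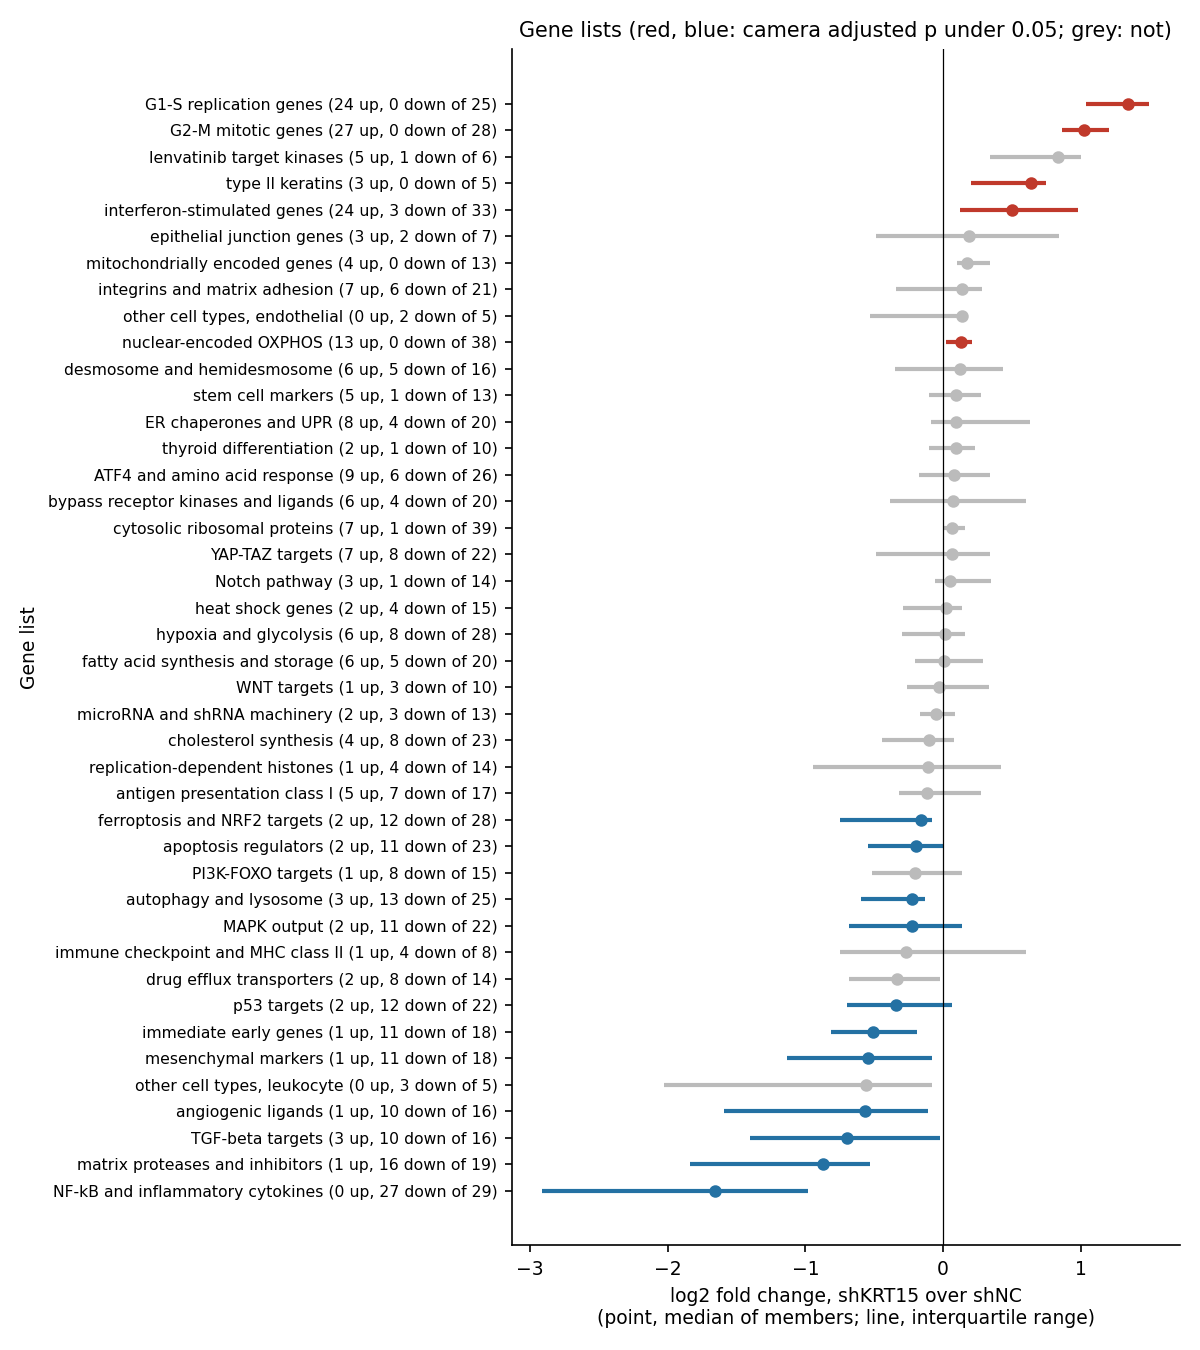
Log2 fold change (shKRT15 over shNC) of 42 gene lists, with the median of the tested members as a point and the interquartile range as a line, and the counts of members past the threshold beside each name. Lists with a camera adjusted p under 0.05 are red or blue. NF-kB and inflammatory genes lie lowest at −1.66 and G1-S replication genes highest at 1.34.

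Matrix and mesenchymal genes fell. Of 19 matrix proteases and inhibitors, 16 fell and only TIMP2 rose, with a median of −0.87 (adjusted p = 8.69e-07, and adjusted p = 0.152 with an estimated correlation). MMP1 (−3.07 ± 0.11) and the plasminogen activators PLAU (−1.81 ± 0.07) and PLAT (−1.53 ± 0.07) were among those that fell, with the same counts adjusted over the list alone. Of 18 mesenchymal markers, 11 fell, among them TAGLN (−1.94 ± 0.10), COL5A1 (−1.25 ± 0.08) and SPARC (−0.86 ± 0.07), and only VIM (0.19) rose (12 and 2 adjusted over the list alone). VIM lost its call with the GC content and length trend removed (adjusted p = 0.251) and without shNC replicate 1 or 2 or shKRT15 replicate 1 or 3 (0.0595 to 0.132). The mesenchymal list had adjusted p = 0.000772, and adjusted p = 0.311 with an estimated correlation. Of 16 TGF-beta targets, 10 fell, among them CDKN2B (−2.20 ± 0.08) and PMEPA1 (−1.36 ± 0.08), and ID2, LTBP3 and SMAD6 rose (11 and 3 adjusted over the list alone). SMAD6 lost its call with the trend removed (adjusted p = 0.0871) and without the same libraries as VIM (0.0511 to 0.0848). The TGF-beta list had adjusted p = 0.00197, and adjusted p = 0.215 with an estimated correlation. Fibroblast markers had 4 tested members, too few for a list test: LUM (−2.77 ± 0.24), COL1A1 (−1.52 ± 0.17) and MFAP5 (−2.03 ± 0.29) fell and PDGFRB rose.

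Adhesion lists held rises and falls and none was called by camera, though fry called the epithelial junction list lower (adjusted p = 0.00034). Of 21 integrin and matrix adhesion genes, 7 rose, with SDC1 (1.13 ± 0.07) first, and 6 fell, with ITGA1 (−2.07 ± 0.09), ITGA5 (−0.87 ± 0.07) and ITGA2 (−1.06 ± 0.12) first. Of 16 desmosome and hemidesmosome genes, 6 rose, led by PKP3 (0.96 ± 0.09), and 5 fell, among them DSC2 (−1.49 ± 0.13). Of 7 epithelial junction genes, CLDN1 (−0.98 ± 0.07) and CLDN4 (−4.49 ± 0.42, from 2.60 to 0.113 CPM) fell, and TJP1, TJP3 (1.42 ± 0.34) and CRB3 (1.53 ± 0.44) rose, the last losing its call without shKRT15 replicate 3 (1.06, adjusted p = 0.117) and TJP1 without shNC replicate 2 or 3 or shKRT15 replicate 1 or 2 (adjusted p = 0.0897 to 0.144). Of 22 YAP-TAZ targets, 7 rose, with IGFBP3 (1.16 ± 0.07) first, and 8 fell, with NT5E (−1.08 ± 0.07), F3 (−1.78 ± 0.13) and CCN1 (−0.87 ± 0.07) first. All 4 lists kept these counts adjusted over the list alone, and in each the median was above 0 and the mean below it. The camera direction followed the median for the integrin and desmosome lists and the mean for the junction and YAP-TAZ lists.

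Lists for p53, cell death, iron and lysosomes fell by smaller amounts. Of 22 p53 targets, 12 fell, including PLK3 (−1.39 ± 0.11), TIGAR (−1.11 ± 0.09) and GDF15 (−0.86 ± 0.08), FDXR and XPC rose, and CDKN1A was at −0.07 ± 0.07, or −0.23 (adjusted p = 0.00799) with the GC content and length trend removed (list adjusted p = 0.0114, and adjusted p = 0.152 with an estimated correlation). Of 23 apoptosis regulators, 11 fell and BCL2L11 and BCL2L1 rose (adjusted p = 0.0197, and adjusted p = 0.167 with an estimated correlation). The falling members included the anti-apoptotic BCL2A1 (−3.02 ± 0.12) and BIRC2 (−1.02 ± 0.08) as well as the pro-apoptotic PMAIP1 (−0.93 ± 0.08) and BMF (−1.54 ± 0.13). Of 28 ferroptosis and NRF2 targets, 12 fell, led by HMOX1 (−1.40 ± 0.07), FTL (−1.01 ± 0.07) and FTH1 (−1.05 ± 0.08), and AIFM2 and AKR1B10 rose (adjusted p = 0.0114, and adjusted p = 0.152 with an estimated correlation). AIFM2 lost its call with the trend removed (adjusted p = 0.372) and without shNC replicate 1 or 2 or shKRT15 replicate 1 or 3 (0.0601 to 0.14), and AKR1B10 without shNC replicate 2 or shKRT15 replicate 2 or 3 (0.0708 to 0.128). These 3 lists kept their counts adjusted over the list alone. Of 25 autophagy and lysosome genes, 13 fell, among them the autophagy receptor SQSTM1 (−1.08 ± 0.07), ATP6V0D2 and GABARAPL1, and ATG16L1, CTSD and GPNMB rose (14 and 3 adjusted over the list alone). CTSD was not called with the trend removed (adjusted p = 0.1665), nor GPNMB without shNC replicate 2 (0.0879) or 3 (0.0716). The last list had adjusted p = 0.00197, and adjusted p = 0.43 with an estimated correlation.

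Stress and metabolic lists were not called by camera, except oxidative phosphorylation. Fry, which does not compare a list with other genes, called ER chaperones (adjusted p = 0.0121) higher, and heat shock (0.0196) and cholesterol synthesis genes (0.008) lower. Of 20 ER chaperone genes, 8 rose, with PDIA4 (0.92 ± 0.07) and HSPA5 (0.80 ± 0.07) leading, and 4 fell, with DNAJB9 (−1.04 ± 0.08) first. Of 26 ATF4 targets, 9 rose, led by PHGDH (1.11 ± 0.08), and 6 fell, led by STC2 (−0.93 ± 0.07). Of 15 heat shock genes, HSP90AA1 (0.32 ± 0.07) and HSPD1 (not called without shNC replicate 1 or 2 or shKRT15 replicate 1 or 3, adjusted p = 0.0563 to 0.128) rose and 4 fell, led by CRYAB (−1.72 ± 0.14). Of 28 hypoxia and glycolysis genes, 6 rose, led by ENO1 (0.79 ± 0.07), and 8 fell, among them ADM (−1.67 ± 0.13) and VEGFA (−0.69 ± 0.07). Of 23 cholesterol synthesis genes, 4 rose and 8 fell, led by HMGCS1 (−0.75 ± 0.07), against 4 and 9 adjusted over the list alone. Of 20 fatty acid genes, 6 rose, led by PLIN2 (0.70 ± 0.07), and 5 fell, led by FABP5 (−0.47 ± 0.08). In the heat shock and hypoxia lists the median lay just above 0, and the mean and the camera direction below it. Apart from cholesterol synthesis, these lists kept their counts adjusted over the list alone. Of 38 nuclear-encoded genes of oxidative phosphorylation, 13 rose and none fell (11 and 0 adjusted over the list alone), with SDHA (0.44 ± 0.07) and COX8A (0.45 ± 0.09) as examples. This list was called (median 0.13, adjusted p = 0.03, and adjusted p = 0.849 with an estimated correlation), but not without shNC replicate 1 (adjusted p = 0.241), shNC replicate 2 (0.0957) or shKRT15 replicate 2 (0.0768). It was also lost with DESeq2 (median 0.13, adjusted p = 0.109), with fry (0.273) and after removal of the GC content and length trend (median 0.11, adjusted p = 0.297), and the members past the threshold numbered 7, 6 and 23 without shNC replicates 1, 2 and 3.

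Thyroid, stem cell and developmental lists were not called either. Of 10 thyroid differentiation genes, CDH16 and GLIS3 (0.47 ± 0.10) rose and the anion transporter SLC26A7 (−1.13 ± 0.36) fell, its call being lost without shNC replicate 1 (adjusted p = 0.0566) or shKRT15 replicate 3 (0.0692). The thyroglobulin gene TG was at −0.97 ± 0.39 (adjusted p = 0.0512) and was called without shNC replicate 3 (0.0136), with DESeq2 (0.0382), with no filter on low counts (0.0468), with a minimum of 1 CPM (0.0338), among protein-coding genes only (0.0464) and with the GC content and length trend removed (0.0270). Of 13 stem cell markers, 5 rose, among them CD24 (0.60 ± 0.08), and SOX9 (−0.70 ± 0.12) fell. Of 10 WNT targets, with a median of −0.03 and a mean of 0.05, LGR5 rose and CCND1 (−0.27 ± 0.07), DKK1 and DKK3 fell. The calls of LGR5, DKK1 and DKK3 were each lost without 1 library, shKRT15 replicate 1 (adjusted p = 0.0557), shKRT15 replicate 3 (0.0647) and shNC replicate 2 (0.0586). Of 14 Notch pathway genes, HES2, DTX4 and NOTCH3 rose and HES4 fell. NOTCH3 was not called without shKRT15 replicate 3 (adjusted p = 0.0613) or with the trend removed (0.135), nor HES4 without shKRT15 replicate 2 (0.0644). Of 13 genes of the microRNA and hairpin machinery, DROSHA (0.49 ± 0.10) and AGO1 rose and AGO4 (−0.85 ± 0.12), TNRC6A and AGO3 fell. AGO3 was not called without shNC replicate 2 (0.105) or shKRT15 replicate 3 (0.157) or with total-count scaling (0.09045). Counts in these 5 lists were the same adjusted over the list alone.

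Some genes that mark RNA quality or other cell types moved as well. Mitochondrially encoded genes held 4.99 to 5.24% of reads in shNC and 4.86 to 6.55% in shKRT15. Of 13 such genes, 4 rose and none fell, also adjusted over the list alone, with CYTB at 0.34 ± 0.10 (list adjusted p = 0.172, but 0.00857 with 7 members called without shKRT15 replicate 2, and 0.0264 with the GC content and length trend removed, at a median of 0.24). Only 1 mitochondrial gene passed without shNC replicate 1, and 2 without shNC replicate 2 or 3 or shKRT15 replicate 3. Of 39 cytosolic ribosomal protein genes, 7 rose, with RPL35 (0.45 ± 0.08) and RPS2 (0.40 ± 0.07) first, and RPL11 fell, against 3 and 0 adjusted over the list alone. The ribosomal list was not called (adjusted p = 0.188), but was called without shNC replicate 3 (0.00116, 19 members). With shNC replicate 2, shKRT15 replicate 1 or shKRT15 replicate 3 left out, 4, 5 and 3 ribosomal genes passed, and RPL11 lost its call in the last 2 of these and without shNC replicate 3. RPL11 also lost it with total-count scaling (adjusted p = 0.0757). The 10 most abundant genes held 8.70 to 8.98% of reads in shNC and 6.73 to 8.25% in shKRT15. Of 5 tested endothelial markers, with a median of 0.14 and a mean of −0.44, TIE1 (−2.62 ± 0.20) and ROBO4 (−0.53 ± 0.17) fell, also adjusted over the list alone (fry adjusted p = 0.0153, lower), and the call of ROBO4 was lost without shNC replicate 2 (adjusted p = 0.0975), shKRT15 replicate 1 (0.0626) or shKRT15 replicate 3 (0.0561). Of the erythroid and serum genes only AFP was tested (−1.47 ± 0.73, adjusted p = 0.114).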

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

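Upper-quartile and total-count scaling and leaving out the 50 most abundant or the mitochondrially encoded genes were chosen after the data were seen, and the other settings were planned. The counts of higher and lower genes, at either size limit, stayed within 1.5 times their values in all 18 refitted settings, with 5194 to 6747 genes called in all, against 6464. KRT15 was lower and called in each, from −0.53 (GC content and length trend removed) to −0.30 (without shNC replicate 3). Total-count scaling gave 58% higher among called genes, against 49%. With the trend removed, 5262 of the 6464 calls were still made in the same direction and 26 had the opposite sign. The number of lists called higher was 5 and ranged from 3 (without shNC replicate 2) to 6 when 1 library was left out. An estimated correlation, which leaves the fold changes as they are, called 2 lists higher and 1 lower (against 11), and fry, which does not compare a list with other genes, called 19 lower. Directions turned with the trend removed for EGFL7 (−0.0429), IL33 (0.0473), LCN2 (−0.0345), the thyroid list (−0.0219) and the ribosomal list (−0.0175), and with total-count scaling for KRT7 (0.0287), none of them called there. They also turned when 1 library was left out for KRT17 (−0.11 to 0.54), KRT7 (−0.135 to 0.0332), CCNE1 (−0.174 to 0.0202), ITGAM (−0.0752 to 0.532) and the IL33 log2 fold change (−0.578 to 0.0582). The cause was not tested. Over all settings, 93 values of single named genes fell below the threshold in the same direction, 15 passed it newly and 4155 stayed as they were. For lists these numbers were 25, 12 and 417. Of 18 lists described by counts alone, 10 changed direction in some refit (smallest adjusted p 0.563), and 2 were called by camera in 1 refit each, checkpoint genes with DESeq2 (adjusted p = 0.00747) and efflux transporters with the trend removed (0.0498). The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.164, −0.016 and 0.146, and not every library matched its own number best (shNC replicate 2 matched shKRT15 replicate 1 at 0.113). The replicate number as a block called 6733 genes, with 6392 of the 6464 calls kept, and put KRT15 at −0.38. Depth limited genes near the floor: with 4 reads or fewer in a group, KRT14 and KRT19 allowed no fold change.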

Other observations

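The tests on reads of keratin relatives, on leukocyte transcripts, on the share of lower genes with 1 seed match, on the AU-rich element and on Reactome terms were chosen only after the result was seen. The tests of KRT15 over scalings and without the 50 most abundant genes used settings added after the data were seen. The other tests were set down before their results were seen.

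Reactome terms, as annotated in the deposited table, were also tested, and they may hold the same genes as the lists above. Of 1074 terms with 15 to 200 tested genes, camera called 137 higher and 22 lower at its preset correlation. With an estimated correlation it called 0, with 81 higher and 10 lower at an unadjusted p under 0.05. The leading term was DNA strand elongation, with 31 of 32 genes higher and a median of 1.01 (adjusted p = 1.07e-13, and adjusted p = 0.422 with an estimated correlation). The leading lower terms were interleukin-10 signalling, with 25 of 33 genes lower and 5 higher (median −1.66), and binding of chemokines to their receptors, with 11 of 17 lower and 3 higher (median −2.04). Overlap of these terms with the inflammatory list was not counted, and lower transcripts of a term do not measure signalling through the pathway it names. Collagen degradation had 21 of 39 genes lower and 4 higher (median −0.53). The term for regulation of mRNA stability by proteins that bind AU-rich elements was not called, with 29 of 85 genes higher and 11 lower (median 0.08, adjusted p = 0.295). Of single genes chosen after their values were seen, ZFP36 (−0.75 ± 0.10) and ZFP36L1 (−0.47 ± 0.07), which speed decay, fell, and ZFP36L2 (1.20 ± 0.08), of the same family, and ELAVL1 (0.49 ± 0.08), which stabilises such mRNA, rose.

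While KRT15 itself fell by 23.4%, the real split of the 6 libraries called 6464 genes and the highest of the other 9 splits called 0 (449 at an unadjusted p under 0.05), but as 1 of 10 splits gave as many genes, the splits are too few for a share under 0.05. Each of the other 9 also mixed libraries of both groups. The group difference then widened the spread within a split, so 0 calls there give no rate of chance calls. A larger fall hidden by relatives was argued against, since KRT14, KRT16, KRT17 and KRT19 held 2.70% as many reads as KRT15 in shKRT15. The lowest KRT15 log2 fold change over 5 scalings was −0.386. These scalings put the median of all genes between −0.00218 and 0.0588, so they differ too little to show a much larger fall. The fall was largest with the GC content and length trend removed, as given above, a setting that was not among the 5. Copy number differences of 0.4 (log2) were argued against by 127 windows of 100 neighbouring genes (largest distance of a median 0.291 ± 0.0519, SE, and highest distance plus 2 SE 0.403, or 0.392 with the GC content and length trend removed), and smaller or partial ones stay open. Hairpin seed matches cannot be told apart from other causes. The most negatively shifted of 3' UTR 7-mers (ATTTATT, statistic −6.95, against −4.4 in 100 shuffles) occurs in KRT15 but was 1 of 6 beyond the shuffles on that side. The other 5, which do not occur in KRT15, share its AU-rich core. TTTTCTT, also in KRT15, was the 1 beyond the shuffles on the positive side (4.78 against 4.67). As 29.6% of scanned 7-mers occur in KRT15 transcripts, a match there says little by itself. The median shift of ATTTATT was only −0.0376 (log2). It was 15.1 percentage points more frequent among lower genes (49.6 against 34.5%), too few to account for most of them. That excess was below the 15.9 points of TATATTT, which is absent from KRT15.

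The fall of NF-kB and inflammatory cytokine genes was set against 3 technical explanations. From shNC to shKRT15, reads of the leukocyte genes PTPRC (43 to 0), LYZ (58 to 6) and LST1 (34 to 19) fell in number and those of CD14 (19 to 20) and ITGAM (38 to 53) did not, so a trace of such cells in shNC stays open. As the source of the fall, leukocytes were argued against, since the 29 list members lost 2.36% of all reads and these 5 genes had a median of 0.355 CPM in shNC, at most 15.1 CPM in cells that supplied that share. The list median was −1.73 without the GC content and length trend, which therefore does not account for the fall. It was −1.71 without the 50 most abundant genes. Leaving those genes out put the median of all genes at 0.0196, against −0.0013. Those genes thus had little effect on the scale, and that setting could hardly have moved the list. A response to the KRT15 hairpin may be the source, as a hypothesis, but an off-target of the hairpin and culture conditions that differed with the group stay open.

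The rise of replication and mitotic genes was likewise not accounted for by GC content and length (lower of both list medians 1.15 after the trend was removed). That value was 1.05 without the 50 most abundant genes, but leaving them out hardly moved the scale, as given above. Fewer cells in a senescent-like arrest in shKRT15 cannot be told apart from a faster cycle, since only 1 of 3 arrest genes chosen for the test fell past the threshold. CDKN2B, which is also on the TGF-beta list, fell (−2.20 ± 0.08), while CDKN1A (−0.07 ± 0.07, adjusted p = 0.414, but −0.23 and called with the GC content and length trend removed) and GLB1 (−0.09 ± 0.09, adjusted p = 0.436) did not pass the edgeR test. Outside the test, CDKN2A fell by 0.23 ± 0.07 (adjusted p = 0.0173, but 0.058 with total-count scaling and 0.0894 and 0.0577 without shKRT15 replicate 1 and 2), and LMNB1 (1.41 ± 0.10) and HMGB2 (0.85 ± 0.08), which are low in senescent cells, rose. CDKN2A, LMNB1 and HMGB2 were chosen after their values were seen and do not decide between fewer arrested cells and a faster cycle. Cell density at harvest was not analysed here and may differ between the groups.

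The 7-mers above led to the hypothesis that transcripts with an AU-rich element fell as a class. Without the inflammatory list, the 1212 genes with the nonamer TTATTTATT in the 3' UTR had a median log2 fold change of −0.157, against 0.015 for genes without it, and a median difference of −0.089 after GC content and length. With 2 or more sites (293 genes) the difference was −0.061. The nonamer holds 7-mers picked from the same fold changes, so these values restate the pattern and do not test it, and whether such transcripts fell as a class stays open. No independent data on mRNA decay were used here.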
